A study of Rattus norvegicus with 10 samples.

How the data were processed

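Gene expression was measured on 10 Affymetrix Rat Genome 230 2.0 arrays, 5 of biopsies and 5 of total tumours, from 5 mammary tumours induced with 100 mg/kg DMBA by mouth. Per the labels, samples were kept in a preservative and frozen before RNA extraction, and tumours were chosen by histology. The deposited values are log2 signals of probe sets, 1 column per array, normalized by the authors with Robust Multichip Average (RMA), per the submitters' processing notes. RMA subtracts background, forces the arrays onto 1 distribution and summarises probes into probe sets, so a shift shared by most transcripts of an array is removed. The log2 scale was read from the values, which lie between 2.34 and 14.26. The RMA software version and the chip definition are not given in the sources used here, and GeneSpring GX 7.3 is named per the labels for the statistics. Signals were not transformed again.

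Samples were grouped by the tumour name and moment in the labels, which give the same 5 names in both groups, so the pairing comes from the labels. The correlation of deviations from the group means was above 0.1 in 4 of 5 pairs. It was also above 0.1 in some pairs of different tumours, and the highest, 0.36, was between biopsy 50I1 and total tumour 31D3. The labels do not say whether the tumours came from different rats, so p-values measure the spread between these tumours. The series text calls the late sample a needle sample, while the sample labels call it the total tumour, and the sample labels were followed.

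The array holds 31099 probe sets, of which 57 are controls and were left out. Of the other 31042, 20826 had 1 gene in the platform annotation, 436 had several and 9780 had none listed there, and no gene was named from a probe set with several. Symbols were updated through gene identifiers to the reference gene table. The dimmest 40% by mean log2 signal over all arrays, with a limit of 5.15, were left out, since the series text speaks of a filter near background without a number. This left 18625 probe sets. A gene was represented by its probe set with the highest mean signal, which gave 10793 genes. Of 2960 genes with several tested probe sets, 846 had probe sets that differed in sign.

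Total tumours were compared with biopsies by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the tumour as a block, as the study used a paired test. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Gene lists, 32 in number and with at least 5 measured members, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 848 list genes, 610 were measured. Single measures were tested by exact permutation over pairings, splits or sign flips. Figures were drawn with matplotlib 3.10.9.

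The rule for named genes, the tests of the comparison, the lists and the alternatives were fixed before the data were examined, except 2 alternatives, the hexokinase control and the estimated correlation for lists called only with a tumour left out or no filter, which were added afterwards. Most tests of explanations in the closing part were also chosen afterwards, as said there. The rule took the 12 largest rises and falls among genes past the threshold, or, with fewer than 10 such genes, the 10 largest differences among the 50 smallest p values. To these it added up to 2 genes with the smallest p from each list described, and 12 genes of receptors, growth, keratins, milk and housekeeping. Mast cell genes other than Tpsab1 and Cma1 were named because their number passing adjusted over the list alone was small. Kit and Mcpt1, which did not pass, were named beside them, and all of these others were chosen after their values were seen.

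The steps were tested on simulated data built from the real means and residual spread with independent noise. Over 18625 probe sets, 75 of 100 with a log2 change of 1 and 96 of 100 with a log2 change of 2 were recovered, with 11 false calls. In 20 runs over 10793 simulated genes without change, camera made 2 list calls in all, and it recovered a list moved by 0.4 in 20 of 20 runs. Real genes of a list vary together, which this simulation leaves out. The noise came from limma's moderated variances, and the planted changes make the adjustment easier to pass. The shares recovered are therefore no measure of power in the real data, where Krt6c, with a difference of 1.99, had an adjusted p of 0.642 in limma.

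Alternatives were other filters, no tumour block, the paired test of the study's methods, trend and array weights, other thresholds and normalizations, other ways to summarise probe sets, and leaving out each tumour in turn. The number of arrays limits the precision.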

Results

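The study measured gene expression in mammary tumours that DMBA, a carcinogenic polycyclic aromatic hydrocarbon, had induced in female Sprague-Dawley rats, an outbred strain. Each of 5 tumours, named 31D3, 32D1, 37I1, 50I1 and 52I4 in the labels, was sampled at 2 moments. A needle biopsy of 0.7 cm by 2.5 mm was taken at an age of 12 weeks, when the tumour had reached 2 cm3, and the whole tumour was collected at 19 weeks. This gave 10 Affymetrix rat arrays, 5 biopsies and 5 total tumours, and the comparison asked how the profile of a tumour at the end differed from that of its own early biopsy. Log2 signals lay between 2.34 and 14.26, and the median of an array lay between 5.99 and 6.11. Pearson correlations between arrays, across all probe sets, lay between 0.952 and 0.989, so no pair of arrays held the same values. The number of arrays limits the precision of every value below.

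The mast cell genes Tpsab1 and Cma1, the circadian clock genes Per3, Per2 and Dbp and the receptor gene Pgr had lower mean signals in the total tumours than in the biopsies, and Krt6c, Dmkn, S100a9 and Ppp2r2b had higher ones, but no single gene passed the test over all probe sets. No list of clock genes was fixed beforehand, and the calls of gene lists given further on were lost with an estimated correlation, with a lowest adjusted p = 0.427. Tpsab1, a mast cell tryptase, had a log2 signal of 10.40 ± 0.67 (SD, n = 5) in the biopsies and 9.02 ± 1.31 (SD, n = 5) in the total tumours, a difference of -1.39 (SE 0.297). Cma1, a mast cell chymase, differed by -1.20 (SE 0.217). The clock genes Per3, Per2 and Dbp differed by -1.37 (SE 0.232), -1.30 (SE 0.224) and -1.28 (SE 0.261), which for Per2 rests on 1 of its 2 probe sets, the other having the opposite sign and the mean of both being -0.63. Pgr, the progesterone receptor, had a log2 signal of 8.33 ± 0.66 (SD, n = 5) in the biopsies and 7.06 ± 0.56 (SD, n = 5) in the total tumours.

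On the higher side, Krt6c, a keratin of stratified epithelium, had a log2 signal of 6.46 ± 0.94 (SD, n = 5) in the biopsies and 8.45 ± 0.36 (SD, n = 5) in the total tumours, a difference of 1.99 (SE 0.307) or 3.98-fold. Dmkn, which encodes the skin protein dermokine, differed by 1.42 (SE 0.252). S100a9, a calcium-binding protein abundant in neutrophils, differed by 1.60 (SE 0.402), and Ppp2r2b, a regulatory subunit of a protein phosphatase, by 1.25 (SE 0.174). Each of these 10 genes, the largest differences among the 50 smallest p values, went the same way in 5 of 5 pairs. A choice by small p in a paired fit favours such agreement, so it adds no support. The same holds for list members named below for their small p. None passed after adjustment, with an adjusted p of 0.642 in limma for all 10.

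**Figure D1:**
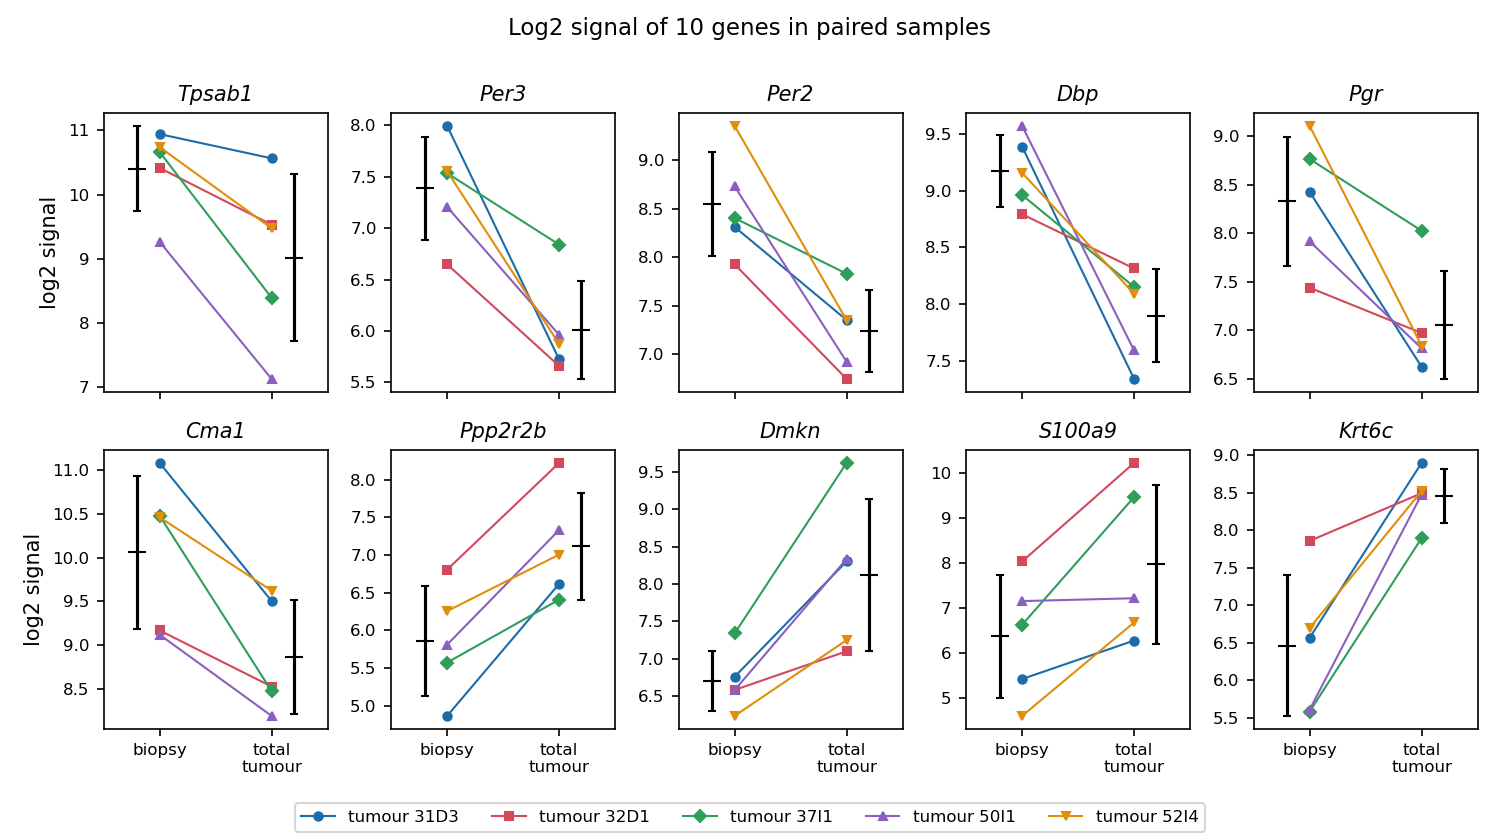
Log2 signal (y axis) of 10 genes in the biopsy and the total tumour (x axis) of each of 5 tumours, joined by lines, with black bars for the mean and SD of each group of 5 arrays; y axes differ between genes and do not start at 0. Tpsab1, Per3, Per2, Dbp, Pgr and Cma1 were lower in the total tumour in 5 of 5 pairs, and Ppp2r2b, Dmkn, S100a9 and Krt6c were higher in 5 of 5 pairs, with an adjusted p of 0.642 for each.

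Over 18625 probe sets, 0 passed an adjusted p under 0.05 in limma, and 1133 had an unadjusted p under 0.05, where chance gives 931.25. Of these, 875 were lower and 258 higher in the total tumours. Probe sets with no gene listed gave 381 of them out of 3545 tested, and those with a single gene 738 out of 14739. The excess over chance thus lay mostly with probe sets that have no gene listed. Over 10793 genes, 0 passed and 450 had an unadjusted p under 0.05, where chance gives 539.65. The paired test that the study's methods name gave 1013 probe sets at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg adjustment. Of the 10793 genes, 629 went the same way in 5 of 5 pairs, which is 5.83% where chance gives 6.25%. Age, moment of sampling and way of sampling went together with the group, and the arrays of each group carry their own run of consecutive numbers in the labels, so a batch of arrays and the group cannot be told apart.

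Among the receptor, growth, keratin and milk genes fixed beforehand, Pgr differed by -1.27 (SE 0.274). The receptor gene Erbb2 had a difference of -0.35 (SE 0.291), which was -0.11 without tumour 31D3 and -0.66 without 32D1, and the prolactin receptor Prlr one of -0.27 (SE 0.280), which was -0.01 without 31D3, -0.55 without 32D1 and -0.17 with the mean of probe sets. The proliferation marker Mki67 differed by 0.22 (SE 0.388) and the cyclin Ccnd1 by 0.04 (SE 0.126), and both turned sign without tumour 31D3, to -0.06 for each. Mki67 was at most 0.54 (without 32D1) and Ccnd1 at most 0.13 (without 52I4). The luminal keratin Krt8 was higher by 0.37 (SE 0.144) and the basal keratin Krt5 by 0.09 (SE 0.0953), or 0.04 without 31D3 and 0.13 without 32D1. The growth factor Vegfa differed by -0.14 (SE 0.382), and by 0.26 without tumour 52I4 and -0.39 without 31D3. The milk protein Csn2 differed by -0.43 (SE 1.87) and varied with an SD of 4.02 within each group, and its difference was 1.63 without tumour 32D1 and -1.81 without 50I1. The estrogen receptor Esr1 had a mean log2 signal of 4.68, under the limit of 5.15 for testing, and Hras and Gapdh were read only by probe sets shared with other genes. The Gapdh control probe sets of the array, the housekeeping reference of the study, were higher by 0.27 (SE 0.171) in the total tumours, in 4 of 5 pairs (exact sign-flip permutation p = 0.1875, two-sided), and those of beta-actin differed by -0.04 (SE 0.0439; exact p = 0.375).

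The 32 gene lists were fixed before the data were examined. With a preset correlation, camera called 16 lists higher and 3 lower in the total tumours, 19 in all. With an estimated correlation it called 0, with a lowest adjusted p = 0.427, and 3 lists had an unadjusted p under 0.05. The directional test of fry called 0 lists as well, with a lowest adjusted p of 0.211. Without tumour 31D3 camera called 10 lists and without tumour 37I1 it called 8. Only 3 of the 32 lists moved the same way in 5 of 5 pairs. These were mast cell and eosinophil (the mast cell list below), myoepithelium (with only -0.00486 in 50I1) and skin keratinocyte. Chance gives such agreement for 6.25% of lists, so 3 of 32 does not stand out.

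The mast cell list also named eosinophil genes, but Epx and Prg2, for example, were not among its measured members. Its measured members had a mean log2 difference of -0.69 (SE 0.198 over 5 pairs). With no filter on signal the list had 17 members and a mean of -0.35, so the dim members did not share the size of this fall. Of 11 measured members, 10 were lower, 8 of them at an unadjusted p under 0.05, and 7 fell when adjusted over the list alone, while 0 passed over all probe sets. These 7 were Tpsab1, Cma1, the protease genes Cpa3 (-0.83, SE 0.187) and Tpsb2 (-0.86, SE 0.272), the IgE receptor genes Ms4a2 (-0.85, SE 0.279) and Fcer1a (-0.74, SE 0.261), and Hdc (-0.74, SE 0.257), which makes histamine. The receptor Kit, which other cells also express, differed by 0.11 (SE 0.358), and the protease gene Mcpt1 by -0.19 (SE 0.570), lower in only 2 of 5 pairs. Camera called the list with an adjusted p of 5.46e-08 (adjusted p = 0.427 with an estimated correlation), and the call was kept whichever of the 5 tumours was left out.

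Contractile gene lists had lower means in the total tumours, though not in every member or, for smooth muscle, in every tumour. The smooth muscle list had a mean log2 difference of -0.23 (SE 0.114), with 11 of 13 members lower, 3 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone. The myoepithelium list, which shares actin and other contractile genes with it, differed by -0.18 (SE 0.0652), with 12 of 16 members lower. Tagln differed by -0.38 (SE 0.0930, lower in 5 of 5 pairs), Acta2 by -0.44 (SE 0.165) and Lmod1 by -0.46 (SE 0.154). Camera gave the lists adjusted p values of 6.43e-04 and 0.00221 (adjusted p = 0.427 with an estimated correlation for each), and without tumour 37I1 these became 0.134 and 0.0893, with means of -0.13 for each. In the same tumour the skeletal muscle list differed by -0.64, and by -0.63 in 50I1, and the skeletal muscle actin Acta1 was high in the biopsies of 37I1, at 11.93, and of 50I1, at 8.13.

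Genes of the skin keratinocyte list had a mean log2 difference of 0.24 (SE 0.050), a median of 0.10 and 11 of 14 members higher. Of these, only Krt6c passed adjusted over the list alone, and Sbsn, a secreted protein of the epidermis, differed by 0.52 (SE 0.254), or 0.31 without 37I1. Camera called the list with an adjusted p of 0.0156 (adjusted p = 0.427 with an estimated correlation), and the call was lost without tumour 50I1 (adjusted p = 0.121) and with quantile normalization (adjusted p = 0.0507). The neutrophil list had 5 measured members, 4 of them higher, with a mean of 0.65 (SE 0.394), a median of 0.22 and a difference of -0.68 in 50I1. S100a8, which pairs with S100a9, differed by 1.52 (SE 0.427), and both genes passed adjusted over the list alone. The list's adjusted p was 0.0202 (adjusted p = 0.647 with an estimated correlation), 0.0688 without tumour 31D3, 0.346 without tumour 37I1 and 0.0907 with no tumour block. Its mean was 0.37 without 37I1 and 0.99 without 50I1.

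Proliferation genes were higher on average but split by tumour. All 38 measured members had a higher mean in the total tumours, with a list mean of 0.37 (SE 0.381). The list was higher by 1.08 in 31D3, 0.88 in 50I1 and 1.02 in 52I4, and its differences were -0.59 in 32D1 and -0.52 in 37I1. E2f1, a transcription factor of the cell cycle, differed by 0.56 (SE 0.207) and the mitotic kinase Aurka by 0.40 (SE 0.211), and 0 members passed adjusted over the list alone. Camera's adjusted p was 1.72e-07 (adjusted p = 0.737 with an estimated correlation). The mean was 0.20 without 31D3, 0.62 without 32D1, 0.60 without 37I1, 0.25 without 50I1 and 0.21 without 52I4, and the list was called in each.

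Stromal and immune genes went opposite ways in different tumours. The fibroblast and collagen list had a mean difference of 0.43 (SE 0.616), from 2.00 in 37I1, 1.22 in 52I4 and 0.87 in 31D3 to -0.56 in 32D1 and -1.40 in 50I1. The mean signal of this list spanned 7.66 in 37I1 to 10.87 in 50I1 in the biopsies, and 9.47 to 10.58 in the total tumours. The largest differences thus went with the lowest and the highest biopsy. Biopsy 37I1 was also the lowest biopsy for the complement (7.65), T and NK cell (5.20) and macrophage (8.27) lists. Whether the tumours changed or the needle biopsies were uneven was not tested. The fibroblast list member Fbln1, a matrix protein, was higher by 1.07 (SE 0.306) in 5 of 5 pairs. Camera's adjusted p of 0.00249 for the fibroblast list (adjusted p = 0.741 with an estimated correlation) became 0.0596 without 31D3, 0.761 without 37I1 and 0.174 without 52I4. Its mean was 0.67 without 32D1, 0.04 without 37I1, 0.88 without 50I1 and 0.23 without 52I4. The complement and the protease lists followed the same tumours, with differences of 1.78 and 1.26 in 37I1 and of -1.07 and -0.75 in 50I1. Their mean differences were 0.40 (SE 0.487) and 0.35 (SE 0.357), and their adjusted p values 0.00221 and 0.00366 (adjusted p = 0.737 with an estimated correlation for each), which became 0.0607 and 0.0586 without 31D3, and 0.761 and 0.616 without 37I1. Their means were 0.23 and 0.24 without 31D3, 0.05 and 0.13 without 37I1, and 0.76 and 0.63 without 50I1. Cfi, a complement protease, differed by 0.80 (SE 0.254) and the collagenase Mmp13 by 1.10 (SE 0.535), or 0.60 without 52I4.

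The T and NK cell list was higher by 1.79 in 31D3 and 1.68 in 37I1 and differed by -0.26 in 32D1, -1.30 in 50I1 and -0.70 in 52I4. Its adjusted p was 0.158, and it was called higher without 50I1 (0.63, adjusted p = 1.64e-04) and without 52I4 (0.48, adjusted p = 0.00160). These calls were lost with an estimated correlation (adjusted p = 0.598 and adjusted p = 0.687 with an estimated correlation). Cd7, a T cell surface protein, was higher by 0.91 (SE 0.314) in 5 of 5 pairs, or 0.58 without 37I1, and the granzyme Gzma differed by 1.47 (SE 0.613), or 0.78 without 31D3. The mean log2 signal of Gzma in the biopsies was 4.47, under the filter limit of 5.15. The macrophage list differed by 1.67 in 37I1 and -1.41 in 50I1, with a mean of 0.07 (SE 0.520) and an adjusted p of 0.334, while its member Spp1, osteopontin, differed by 0.81 (SE 0.301). That list was called higher without 50I1 (0.44, adjusted p = 9.28e-05) or 52I4 (0.20, adjusted p = 0.0466) and lower without 37I1 (-0.32, adjusted p = 0.0448), and with an estimated correlation these became adjusted p = 0.591, adjusted p = 0.809 and adjusted p = 0.954. The inflammatory cytokine list had a mean of 0.21 (SE 0.420) and its member Cxcl2, a neutrophil chemokine, was higher by 0.76 (SE 0.173) in 5 of 5 pairs. Cxcl2 was also under the filter limit of 5.15 in the biopsies, with a mean log2 signal of 4.79. Camera called that list with an adjusted p of 0.0102 (adjusted p = 0.737 with an estimated correlation), and its mean was -0.04 without 31D3 and -0.04 without 37I1, where the call was lost, and 0.32, 0.47 and 0.34 without 32D1, 50I1 and 52I4. The B and plasma cell list, with 5 measured members, differed by 0.12 (SE 0.231; adjusted p = 0.468), and by 0.06 without 31D3, -0.05 without 37I1, 0.28 without 50I1 and 0.21 without 52I4. Without 31D3 the T and NK cell mean was -0.15 and the macrophage mean -0.08, and without 37I1 the T and NK cell mean was -0.12.

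Interferon, antigen presentation, endothelial and adipocyte genes were called higher by camera. Their mean differences were 0.22 (SE 0.207), 0.12 (SE 0.306), 0.17 (SE 0.345) and 0.34 (SE 0.241), with adjusted p values of 4.79e-04, 0.00797, 0.0411 and 0.0411. The adjusted p with an estimated correlation was 0.737 for interferon, 0.741 for antigen presentation, 0.776 for endothelial and 0.737 for adipocyte genes. Without tumour 37I1 the 4 calls were lost, with adjusted p values of 0.636, 0.761, 0.616 and 0.606. Also lost were antigen presentation without 31D3 (adjusted p = 0.126), endothelial genes without 31D3 (adjusted p = 0.636) or 52I4 (adjusted p = 0.957) and adipocyte genes without 32D1 (adjusted p = 0.183). Endothelial genes were not called with no filter (adjusted p = 0.158), median centring (adjusted p = 0.0943) or quantile normalization (adjusted p = 0.0507), nor adipocyte genes with median centring (adjusted p = 0.0851) or quantile normalization (adjusted p = 0.0594). Without 37I1 the means were 0.03 for interferon, -0.13 for antigen presentation, 0.06 for endothelial and 0.14 for adipocyte genes. Antigen presentation had means of 0.03, 0.31 and 0.23 without 31D3, 50I1 and 52I4, and endothelial genes 0.04, 0.34, 0.43 and 0.00329 without 31D3, 32D1, 50I1 and 52I4. The interferon-induced gene Rsad2 was higher by 0.70 (SE 0.251) in 5 of 5 pairs, or 0.40 without 37I1, and Car3, a carbonic anhydrase abundant in fat and muscle, by 1.94 (SE 0.527) in 5 of 5 pairs.

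Hypoxia, erythrocyte and xenobiotic genes were also called higher by camera. The hypoxia and glycolysis list had a mean of 0.27 (SE 0.269), and its member Angptl4, a regulator of lipoprotein lipase, was higher by 1.12 (SE 0.318) in 4 of 5 pairs. Its adjusted p was 3.09e-04 (adjusted p = 0.737 with an estimated correlation), and 0.454 without 31D3, with means of 0.04 without 31D3 and 0.46 without 32D1. Erythrocyte genes differed by 0.52 (SE 0.245) and xenobiotic and AhR genes, the pathway that DMBA itself engages, by 0.28 (SE 0.133), each with an adjusted p of 0.00188. Erythrocyte genes differed by 1.2 in 31D3, 0.95 in 32D1, 0.38 in 37I1, 0.16 in 50I1 and -0.11 in 52I4, and xenobiotic genes by 0.78 in 31D3, -0.00486 in 32D1, 0.24 in 37I1, 0.13 in 50I1 and 0.27 in 52I4. Both lists were called whichever of the 5 tumours was left out, but without 31D3 the means were 0.34 and 0.16, each with an adjusted p of 0.0486, and with no filter the erythrocyte mean was 0.32. With an estimated correlation the adjusted p was 0.427 for erythrocyte and 0.573 for xenobiotic genes. Within them, Ahsp, a haemoglobin chaperone, was higher by 0.83 (SE 0.289), or 0.48 without 32D1, Akr1b8 by 1.13 (SE 0.408) and Aldh1a3, which makes retinoic acid, by 0.52 (SE 0.131). The mean log2 signal of Ahsp in the biopsies was 4.74, under the filter limit of 5.15.

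Oxidative phosphorylation genes differed by 0.06 (SE 0.0579) and p53 targets by 0.06 (SE 0.0610), with adjusted p values of 0.00519 and 0.0347 (adjusted p = 0.741 and adjusted p = 0.647 with an estimated correlation). Without 31D3 these became 0.0562 and 0.454, and without 32D1 0.0824 and 0.0553. The first was also lost without 52I4 (adjusted p = 0.0875) and with quantile normalization (adjusted p = 0.115), and the other without 37I1 (adjusted p = 0.219), with no filter (adjusted p = 0.158), with no tumour block (adjusted p = 0.136) and with the mean of probe sets (adjusted p = 0.0660). The means were 0.12 and 0.04 without 37I1, 0.10 for each with median centring, 0.02 for p53 targets without 31D3 and 0.04 for oxidative phosphorylation without 52I4. Cdkn1a, the p21 cell cycle inhibitor and a p53 target, was higher by 0.45 (SE 0.120) in 5 of 5 pairs.

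The remaining lists were not called with all tumours and the filter. Epithelial to mesenchymal transition genes differed by 0.15 (SE 0.227), nerve genes by 0.07 (SE 0.0808), heat shock genes by 0.06 (SE 0.171) and ribosomal protein genes by -0.04 (SE 0.0346). Cholesterol synthesis genes differed by -0.06 (SE 0.112), and Acly, which makes acetyl-CoA for lipid synthesis, by -0.39 (SE 0.0991), lower in 5 of 5 pairs. Skeletal muscle genes differed by -0.22 (SE 0.174), immediate early genes by -0.06 (SE 0.258) and milk genes by -0.07 (SE 0.465). The hormone response list had a mean of -0.07 (SE 0.170) and a median of 0.01, and the luminal epithelium list a mean of -0.03 (SE 0.0892), a median of 0.03 and an upward camera direction, so their summaries differ in sign. Pgr is a member of both, and Rerg, an estrogen-regulated GTPase, was higher by 0.86 (SE 0.250) in 5 of 5 pairs. Single tumours moved these means. Transition genes differed by 0.04 without 31D3 or 37I1, nerve genes by 0.13 without 31D3, 0.01 without 32D1 and 0.04 without 37I1, heat shock genes by -0.09 without 31D3 and cholesterol genes by 0.02 without 32D1. Skeletal muscle genes differed by -0.12 without 37I1 or 50I1, immediate early genes by 0.06 without 50I1, milk genes by -0.30 without 50I1, hormone response genes by -0.19 without 37I1 and 0.02 without 52I4, luminal epithelium genes by 0.06 without 31D3 and ribosomal protein genes by -0.00748 without 37I1. Some of these lists were called at the preset correlation with a tumour left out: immediate early genes without 31D3 (-0.29, adjusted p = 1.08e-04), transition genes without 32D1 (0.28, adjusted p = 0.0211) or 50I1 (0.30, adjusted p = 0.0193), cholesterol genes without 50I1 (-0.15, adjusted p = 0.0132), heat shock genes without 52I4 (0.14, adjusted p = 0.0110) and milk genes without 32D1 (0.35, adjusted p = 0.0211). With no filter, nerve genes (0.13, adjusted p = 0.0286) and skeletal muscle genes (-0.15, adjusted p = 0.0319) were called. None of these calls held with an estimated correlation: the adjusted p with an estimated correlation was 0.537 for immediate early, 0.628 and 0.591 for transition, 0.517 for cholesterol, 0.687 for heat shock, 0.714 for milk, 0.572 for nerve and 0.732 for skeletal muscle genes.

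**Figure D2:**
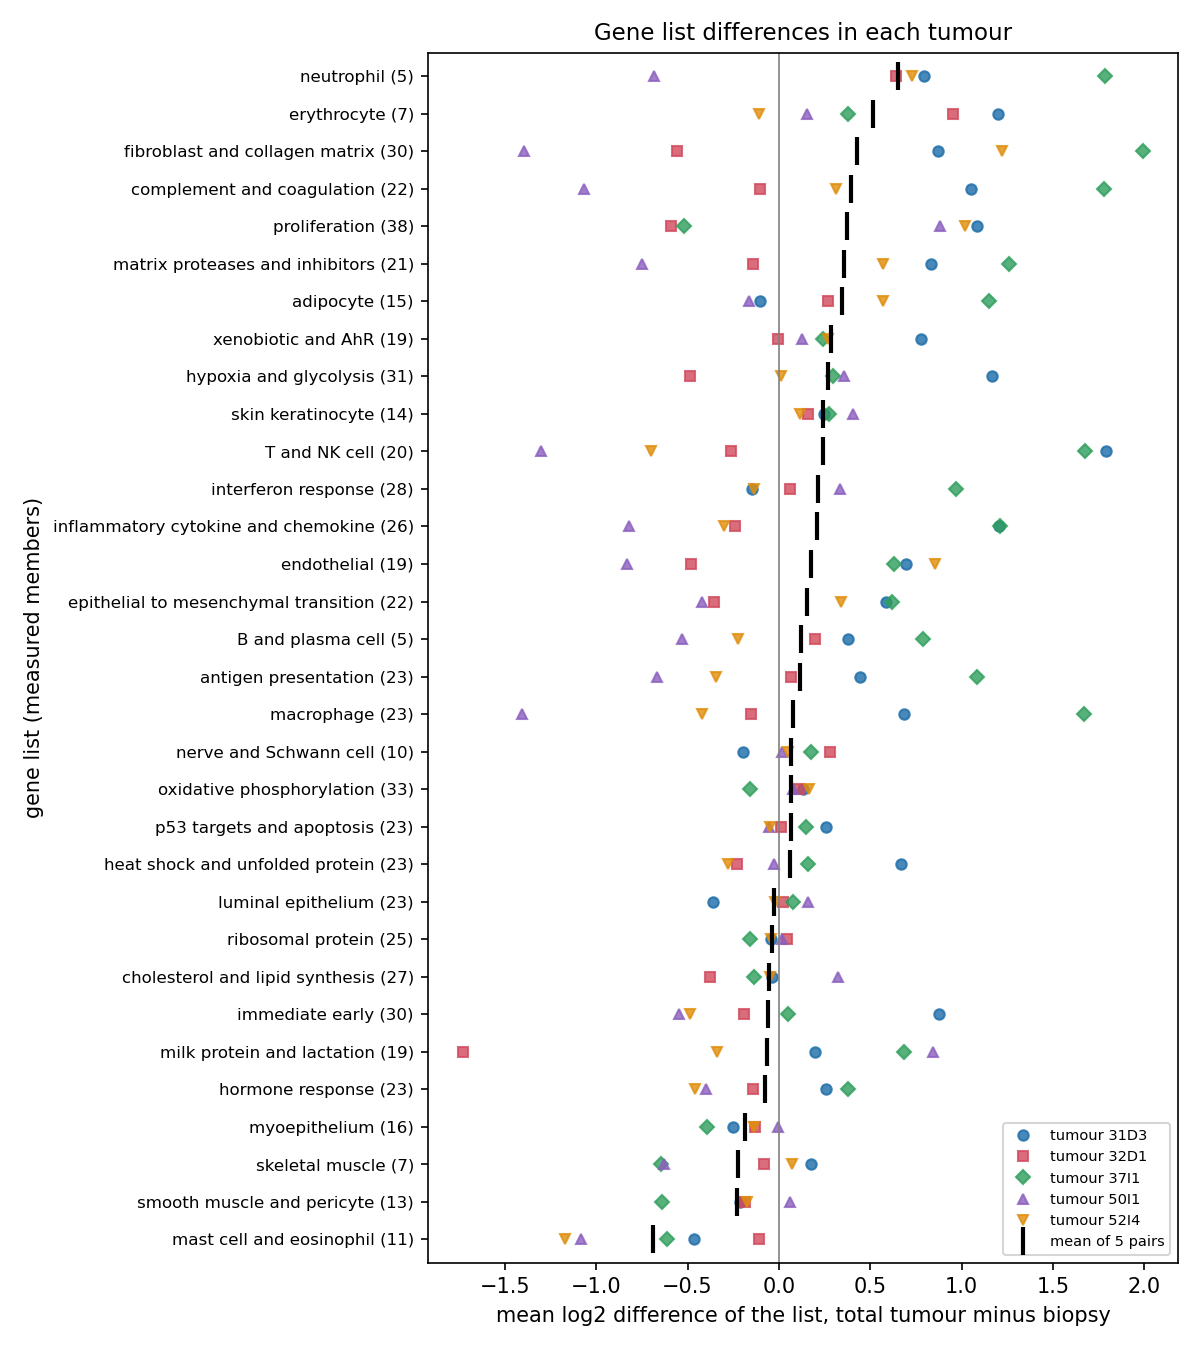
Mean log2 difference of each of 32 gene lists, total tumour minus biopsy (x axis), in each of 5 tumours (coloured symbols) with the mean of the 5 pairs (black bars); the y axis names the lists with their measured members. The mast cell list lies below 0 in 5 of 5 tumours, with a mean of -0.69, and the fibroblast list spans -1.40 in 50I1 to 2.00 in 37I1.

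Samples of the same tumour were more alike than samples of different tumours on average. The deviations of a biopsy from its group mean, correlated across 18625 probe sets with those of its own total tumour, gave Pearson r of 0.20 for 31D3, 0.28 for 32D1, 0.34 for 37I1, -0.21 for 50I1 and 0.34 for 52I4. Probe sets are not independent replicates, so the mean of 0.189 was set against all 120 pairings of biopsies with total tumours (exact permutation p = 0.0417, one-sided; smallest possible 0.00833). Pairs from different tumours averaged -0.0498. Subtracting the group means pushes this value below 0 when the same-tumour mean is above 0, so it is no separate contrast. Of the 5 biopsies, 3 correlated best with their own tumour, while biopsy 50I1 correlated best with total tumour 31D3, at 0.36. With Spearman correlation the mean was 0.171 (exact p = 0.075), and with 4 tumours the exact p was 0.125 without 31D3, 32D1 or 37I1 and 0.167 without 52I4. In limma, 16 probe sets differed between the tumours at an adjusted p under 0.05, and 1955 at an unadjusted p under 0.05, where chance gives 931.25.

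**Figure D3:**
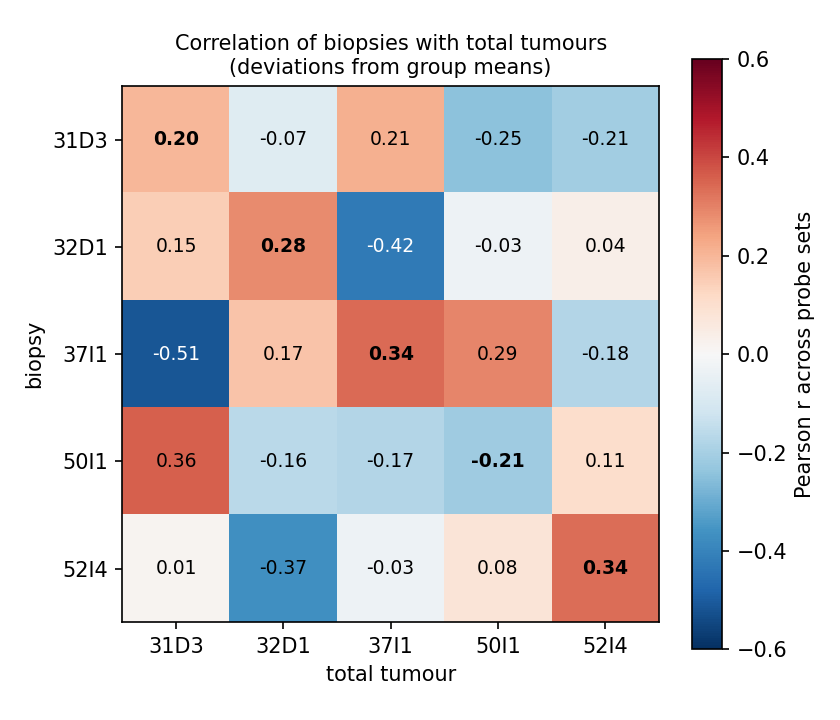
Pearson correlation across probe sets (colour and number in each cell) between each of 5 biopsies (y axis) and each of 5 total tumours (x axis), after subtracting group means, with pairs from the same tumour in bold. The same-tumour values lie between 0.20 and 0.34 except for 50I1, at -0.21.

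No difference in the spread between tumours was found between biopsies and total tumours. The distance of an array from the mean of the others in its group was 0.488 ± 0.0903 (SD, n = 5) log2 units in the biopsies and 0.446 ± 0.0643 (SD, n = 5) in the total tumours (exact permutation p = 0.452, two-sided, 252 splits). These splits ignore the pairing by tumour, and with 5 arrays per group the test cannot show that the spreads are equal. The signal of the 3' minus the 5' probe sets of the Gapdh and beta-actin controls, which grows as RNA degrades, was 0.454 ± 0.0476 (SD, n = 5) in the biopsies and 0.484 ± 0.0774 (SD, n = 5) in the total tumours. The mean difference was 0.0300 (SE 0.0318; exact sign-flip permutation p = 0.4375, two-sided, a test that cannot reach 0.05 with 5 pairs).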

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

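The tests of skin, stroma, shared falls and RNA quality, the difference with no bins and the count of distinct fits below were chosen only after the results they concern were seen. Samples far from the other 4 of their group were looked for in 214 groups of 5 values, and 12 stood apart, 5.61% where chance gives about 5%. Among gene lists, biopsy 32D1 had a mean hypoxia and glycolysis log2 signal of 10.07, above the others at 8.91 to 9.23, and a nerve list signal of 7.57, below the others. Biopsy 37I1 had a T and NK cell list signal of 5.20, where the others lay between 6.83 and 7.35, and biopsy 31D3 a milk list signal of 8.47. Among genes, total tumour 37I1 stood apart from the other total tumours with the muscle actin Acta1 at 9.48, where the others lay between 4.04 and 4.76, while its biopsy had 11.93 and biopsy 50I1 had 8.13. It also stood apart with Per3 at 6.84 and with Pgr at 8.03. The amino acid oxidase Lao1 was high in both samples of tumour 37I1, at 6.66 in the biopsy and 7.47 in the total tumour. The fatty acid transporter Cd36 was low in total tumour 50I1, at 5.56, and Tagln was low in biopsy 32D1, at 12.18. Biopsy 37I1 also had the lowest array median, 5.99.

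Mast cell genes were lower in the total tumours, with a list median of -0.74. In the normalized values, transcripts of similar signal did not share this fall. Of 10000 random lists matched on mean signal, 0 had a median as low, and 95% of them lay between -0.10 and 0.10. The list was taken up for its fall, and RMA itself evens out such trends, so a shared fall before normalization is not decided. A lower keratinocyte list in the total tumours, which skin carried along by the needle would give, was not seen. The list was higher there by 0.24 (SE 0.050), and by 0.11 (SE 0.0368) without Krt6c, which carries much of that mean. Over the 6 other members with a mean signal under 8, among them Krt10 and Loricrin, it was higher by 0.24 (SE 0.0499). This cannot exclude skin in the biopsies, since a rise of such genes in the tumours themselves could hide it. Krt5, for example, had a high signal in both groups, 12.22 in the biopsies and 12.31 in the total tumours. A smaller share of stroma stays open: the fibroblast list was higher by 0.43 on average, but with an SE of 0.616 and a range from 0.04 without 37I1 to 0.88 without 50I1, and its difference from the mast cell list, 1.12 (SE 0.648), is within 2 SE of 0, though not without 32D1 (1.51, SE 0.667) or 50I1 (1.47, SE 0.698); in 3 of 5 pairs (31D3, 37I1 and 52I4) the fibroblast list was higher while the mast cell list was lower, which goes against it there, though a single pair has no error of its own. Of other stromal lists, smooth muscle and pericyte genes differed by -0.23 (SE 0.114) and endothelial genes by 0.17 (SE 0.345), which does not settle it. Age, the moment and the way of sampling stay open as untested, and cannot be parted because each goes with the group in every tumour.

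Probe sets with no gene listed leaned to lower signals in the total tumours. Of 14739 tested with a single gene, 738 had an unadjusted p under 0.05 in limma, and 532 of these were lower (72.1%). Of 3545 tested with no gene listed, 381 did, a larger share, and 337 of these were lower (88.5%). Lower mean signal of such probe sets stays open: within 10 bins of equal mean signal they differed from named ones by -0.0464 (SE 0.0311), which meets the bound of 2 SE set beforehand, but with no bins the difference was -0.0510 (SE 0.0274), so matching on signal moved it by 0.00461 (SE 0.00530). The binned difference rests on tumours 31D3 (-0.154) and 52I4 (-0.0793), with -0.00979, 0.0126 and -0.00181 in 32D1, 37I1 and 50I1, and was -0.0196 (SE 0.0204) without 31D3. More degraded RNA in the total tumours cannot be told apart from no difference: the 3' minus 5' control signal was higher by 0.0300 (SE 0.0318), with 0.00291 without 37I1 and 0.0456 without 32D1, and with the hexokinase control added by 0.0488 (SE 0.0731), which does not exclude a difference of 0.1. No biological explanation was tested.

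The counts were set against other splits of the 10 arrays into 5 and 5. Among the 16 splits that part all 5 pairs, as the real one does, 6 gave at least the real 1133 probe sets at an unadjusted p under 0.05 in limma, with a highest other of 2291, and 2 gave at least the real 19 gene lists, with a highest other of 21, but 16 splits are too few for a share under 0.05. Each of these splits called at least 7 lists, with a median of 13 for those other than the real one. Many calls at the preset correlation thus arose in groupings other than the real one. Each of these still keeps most pairs in a common orientation with the real one. A real shift would be partly left in them, so they do not show calls in its absence. Of 100 splits drawn, 31 gave at least 1133 probe sets, with a highest other of 2822, and 13 gave at least 19 lists, with a highest other of 21, so chance cannot be excluded for these counts. Most of the 100 are no match for the paired comparison: 27 part 1 pair and 60 part 3, and with the tumour as a block they repeat each other, so the 100 hold 54 distinct fits, 19 of them with at least 1133 probe sets and 7 with at least 19 lists. For probe sets and genes past the threshold the real count was 0 (highest other 1 for each), which 100 of 100 splits reach by construction, so this says nothing about chance.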

How the results depend on the processing

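The control with hexokinase and the estimated correlation for lists called only with a tumour left out or no filter (0 of 13 such camera calls held) were chosen after seeing the data; the other alternatives were fixed before. Filters, normalizations, trend, array weights, the block, thresholds and each left-out tumour kept the count of probe sets and genes past adjusted p under 0.05 at 0, and the paired test of the study's methods gave 0 after adjustment and, at an unadjusted p under 0.05, 1013 probe sets (294 higher, 719 lower) and 449 genes. With no tumour block (unpaired) the count was 0 probe sets and 17 lists. An alternative for linear values was not run, since the values are log2. Camera called 0 lists with an estimated correlation and fry 0, against 19; leaving out a tumour gave 8 (without 37I1) to 22 lists (without 50I1), and the cause was not tested. Same-tumour similarity had an exact p above 0.05 with Spearman correlation (0.171; the cause was not tested) and in 4 of 5 sets of 4 tumours (0.147 to 0.192), where fewer pairings limit p; without 50I1 it was 0.306 (exact p = 0.0417).

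The direction given by camera, not the sign of the mean, turned for 2 uncalled lists, and the cause was not tested: luminal epithelium at -0.0420 with no filter and -0.0252 with quantile normalization, and milk at -0.0723 with the mean of probe sets. Leaving out tumours in turn turned the direction of camera, or the sign of the mean as well, for lists with these ranges of the mean: inflammatory cytokine -0.0401 to 0.47, antigen presentation -0.13 to 0.31, endothelial 0.00329 to 0.43, macrophage -0.32 to 0.44, T and NK cell -0.15 to 0.63, milk -0.30 to 0.35, luminal epithelium -0.0713 to 0.0588, hormone response -0.19 to 0.0233, immediate early -0.29 to 0.0632, heat shock -0.0939 to 0.14, cholesterol synthesis -0.15 to 0.0236, ribosomal protein -0.0579 to -0.00748 and skeletal muscle -0.32 to -0.12. Among genes, Csn2 ranged from -1.81 to 1.63, Mki67 from -0.0612 to 0.54, Ccnd1 from -0.0596 to 0.13 and Vegfa from -0.39 to 0.26. Of 72 genes, 0 turned sign with other normalizations, with no block or with the mean of probe sets. Median centring moved all differences by 0.03, under 0.1. Values near background, as for Esr1 and for the biopsies with Cxcl2, Gzma and Ahsp, were limited by signal.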

Other observations

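The test of tumour identity and the comparison of cycling genes with genes of similar signal were chosen only after the results were seen, and the genes in this part were named after their values were seen. Some genes had a higher signal in both samples of a single tumour than in all others, or a lower one. Hoxc9, a homeobox transcription factor, had log2 signals of 8.96 and 7.71 in the biopsy and total tumour of 37I1, where the other arrays lay between 3.75 and 4.47. RT1-Bb, a chain of an MHC class II molecule, had 11.90 and 10.86 in tumour 52I4, where the others lay between 3.28 and 3.72. Ephx2, an epoxide hydrolase, had 7.71 and 7.21 in tumour 37I1 (others 4.64 to 5.38). On the lower side, Elavl1, an RNA-binding protein, had 7.55 and 7.48 in tumour 52I4, where the others lay between 9.65 and 10.49, and the cholesterol transporter Abca1 had 5.69 and 7.00 in tumour 32D1, where the others lay between 9.27 and 10.55.

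In all, 28 probe sets fell into a high and a low level over the 10 arrays, with a gap above 1 log2 unit and 1.5 times the range on either side. Samples of the same tumour had the same level in 85.7% of them, against 59.6% for samples of different tumours (exact p = 0.00833 over 120 pairings, one-sided, the smallest they can give). Of the 28, 17 set both samples of a single tumour apart, 8 of them in 37I1 and 5 in 52I4. This is consistent with a tumour or animal identity kept between biopsy and total tumour, and it bears on the labels' pairing. Sequence variants under the probes, in an outbred strain, were not tested.

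Clock genes had lower mean signals in the total tumours: besides Per2, Per3 and Dbp, the nuclear receptors Nr1d2 and Nr1d1 differed by -0.59 (SE 0.215) and -0.47 (SE 0.245) and Per1 by -0.38 (SE 0.226), while Bmal1, which cycles in the opposite phase, was higher by 0.52 (SE 0.192) in 4 of 5 pairs. These genes had been picked or seen before, so 3 further cycling genes were used to test it: they had a median of -0.36 (SE 0.324, of the medians in 5 pairs), with Tsc22d3 at -0.53 (SE 0.274), Tspan4 at -0.36 (SE 0.275) and Usp2 at 0.03 (SE 0.144). A different circadian phase at the sampling moments may contribute, a hypothesis that is weak at that spread, since the median, for which a bound of -0.3 was set beforehand, was -0.11 without 50I1, -0.28 without 52I4 and -0.60 without 37I1. A fall shared by transcripts of similar signal was not seen in the normalized values. There, 4309 other genes in the same bins of mean signal differed by -0.0101 (SE 0.00453). Less these, the medians of the 9 cycling genes in each pair averaged -0.67 (SE 0.209) over the 5 pairs, which includes the 3 picked for their size. Without those 3 this average of pair medians was -0.32 (SE 0.231), which cannot be told apart from no difference. RMA itself evens out such trends, so a shared fall before normalization is not decided. Time of day is not given in the labels used here, and age, stress hormones and sampling way stay open as untested.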
